A study of Mus musculus with 6 samples.

How the data were processed

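Gene expression was measured on 6 Affymetrix whole-transcript arrays, 1 colour each, from C2C12 cells. C2C12 is an immortalized mouse myoblast line that fuses into multinucleated myotubes when serum is lowered. Per the labels' protocols, cells were differentiated in 2% horse serum, transfected on day 6 with locked nucleic acid (LNA) oligonucleotides at 50 nM, and harvested 24 h later on day 7. Total RNA was extracted with Trizol, purified on columns and accepted only above an RNA integrity number of 8.0, and 100 ng per sample was labelled with biotin. The 3 silenced arrays come from cells given an inhibitor of miR-382-5p and the 3 control arrays from cells given a negative control oligonucleotide. No label says whether the 3 samples of a group were separate cultures, so p-values measure the spread between these samples, which may be partly technical.

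The deposited table holds log2 expression values for 35556 probe sets. The authors used RMA, per the submitters' processing notes; its version, the probe set definition and the software are not given in the sources used here. RMA subtracts background with a model, equalizes the distributions of the arrays and summarizes the probes of a set on the log2 scale. It compresses differences of dim genes toward 0, and differences here may therefore understate those of dim genes. The values were used as deposited, and the arrays' lower quartiles lay between 2.77 and 2.80, their medians between 4.21 and 4.27 and their upper quartiles between 7.04 and 7.08. Detection calls and probe signals were not used here, and the number of arrays limits the precision. No columns of other samples were present.

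Probe sets were named from the platform annotation, which lists 23099 of them: 21218 name 1 gene and 1881 name several. The other 12457 are not listed in it. Of the 21218 single-gene probe sets, 21185 matched a gene of the RefSeq table of assembly GRCm38.p6 by Entrez identifier, and 0 symbols needed an update. Where a gene had several probe sets (1386 genes), the one with the highest mean over all 6 arrays was kept, which gave 18820 genes. Genes whose mean over the 6 arrays lay above the 40th percentile (a log2 level of 3.87) were tested, 11292 in all. The 6 arrays correlated pairwise between 0.985 and 0.995 over these genes and none were identical.

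Silenced and control arrays were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, 2-sided, all 6 arrays, no covariate), with Benjamini-Hochberg adjustment over the tested genes and a threshold of 0.05. Differences are silenced minus control on the log2 scale, and errors of differences are limma's moderated standard errors (SE). Gene lists, 35 with 794 genes, were fixed before the data were examined, as were the design, the threshold and the rule for named genes. The lists hold OXPHOS genes by complex, other mitochondrial functions, energy metabolism, stress responses, muscle genes, proliferation, and markers of undifferentiated myoblasts, fibroblasts, adipocytes, and osteoblasts and chondrocytes. Of their genes, 707 were named by a single-gene probe set and 673 were tested; 34 lists had at least 3 tested members. Lists were tested with camera, which compares the moderated statistics of a list with those of all other genes, with its preset inter-gene correlation of 0.01 and adjustment over the 34 lists. Camera with an estimated correlation and the rotation test fry were alternatives. Fry tests whether a list's genes move on balance one way and does not compare them with other genes.

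The named genes are the 10 with the smallest p in each direction (because no gene passed the threshold), up to 4 members that passed over the list alone from each list that was called or concerns OXPHOS, mtDNA, the mitochondrial unfolded protein response, the integrated stress response or myotubes, or else the 2 with the smallest p, and a preset panel. From that panel, Atf5 and Ddit3 lie on probe sets of several genes and mt-Co1 has no single-gene probe set in the annotation used, so they are not analysed here. Other genes named are said to have been chosen after their values were seen.

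A planned comparison of mtDNA-encoded with nuclear-encoded OXPHOS transcripts was not made, because 0 of the 13 mtDNA-encoded genes were named by a single-gene probe set. A planned test of genes with a 3' UTR match to positions 2 to 8 of miR-382-5p was not made, because no transcript sequence was used here.

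The replicate numbers 1 to 3 occur in both groups. Deviations from the group means correlated between same-numbered arrays at 0.55, 0.35 and 0.42, and all 6 arrays correlated best with the array of their own number in the other group. Deviations of 3 arrays sum to 0, so these correlations are not independent of each other. The numbers were taken to pair the arrays, on the evidence of the data and not of a label. The fit without the number is the main one, as planned, and the fit with the number as a block is given where it changes a call. Alternatives also covered an intensity trend, array weights, repeated quantile normalization, centring, 2 other filters on dim genes, averaging of probe sets, and leaving out each array.

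The gene test was tested on simulated data: normal noise with each gene's measured spread, the measured replicate-number effects, and 200 of 11292 genes changed. For silenced against control without a block, it recovered 17.9% of genes changed by 0.5 log2, 70.1% of those changed by 1 and all 66 changed by 2, with 1 false call. With the replicate number as a block it recovered 31.3%, 65.7% and 93.9%, with 4 false calls. In a second simulation with independent noise, camera with the preset correlation called both lists that had been shifted by -0.1 and -0.3 and 0 of the others, and camera with the estimated correlation called neither. Genes were simulated as independent, so this does not test the preset correlation where genes of a list are correlated. Figures were drawn with matplotlib 3.10.9.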

Results

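Gene expression was profiled in C2C12 myotubes on day 7 of differentiation, 24 h after transfection with an inhibitor of the microRNA miR-382-5p or with a negative control oligonucleotide. The series title places the question in the balance of mitochondrial and nuclear proteins and in the mitochondrial unfolded protein response. There were 3 silenced and 3 control arrays, each carrying replicate numbers 1 to 3. Values are log2 expression levels per array, given as mean ± SD with n = 3 per group unless stated. Inhibitor action on mature miR-382-5p was not measured by these arrays. The probe set for the precursor gene Mir382 read 1.81 ± 0.15 in control and 2.18 ± 0.17 in silenced arrays, a level exceeded by almost all genes (percentile 3.21), and does not check the knockdown.

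At the preset correlation of camera, and only there, interferon-induced genes and genes of both ribosomes, mitochondrial and cytosolic, were lower as groups in silenced arrays. Genes of the contractile apparatus were higher as a group at that setting. Genes of mitochondrial protein import and the proteasome were also lower as groups. These were the 6 lists called of 34 by camera with its preset correlation, 5 of them lower and 1 higher. With an estimated correlation 0 of the 34 lists were called, with a smallest adjusted p of 0.744. In simulated data of independent genes that setting also called neither shifted list, so its lack of calls cannot decide whether these lists changed. That simulation does not test the preset correlation for correlated genes. The estimated correlations were 0.25 for interferon, 0.30 for myotube, 0.11 for mitochondrial ribosome and 0.23 for cytosolic ribosome genes. They were 0.0035 for import and 0.19 for proteasome genes. Where genes correlate beyond the preset, its p-values may be too small. The rotation test fry also called 0 lists (smallest adjusted p = 0.901). No single gene passed limma's adjusted threshold (0 of 11292, smallest adjusted p = 0.487). At an unadjusted p under 0.05 there were 542 genes, 319 higher and 223 lower in silenced arrays. About 565 would be expected if no gene differed and the arrays were independent. Same-numbered arrays varied together, so 565 is not a firm reference for this fit. The 3 other groupings of the arrays that part all same-numbered pairs gave 103, 227 and 422 genes. Without control replicate 3 there were 272 and without control replicate 1 there were 828. With the replicate number as a block the adjusted count was also 0 and the unadjusted count 1168, above 565. Genes that vary together can move such counts, so they do not decide whether genes differed. The 3 silenced values lay apart from the 3 control values for 11.8% of genes, where chance gives 10%.

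The interferon list fell in silenced arrays, with a median difference of -0.32 log2 over 21 tested members (camera, adjusted p = 3.24e-09; adjusted p = 0.744 with an estimated correlation). Of the 21 members, 20 had a lower mean in silenced arrays, and 14 were lower in all 3 same-numbered pairs. Ifit1, an interferon-induced RNA-binding protein, was the only member to pass limma when adjusted over the list alone. It read 5.28 ± 0.32 in control and 4.54 ± 0.10 in silenced arrays, 1.66-fold lower (adjusted p = 0.0434 over the list, 0.871 over all genes). With the replicate number as a block, 11 of the 21 members passed limma adjusted over the list alone and 0 passed over all genes. Among these 11, chosen after their values were seen, were Usp18, a protease that removes the ubiquitin-like modifier ISG15, with a difference of -0.78 ± 0.40 (SE), Ifit3 with -0.67 ± 0.31 (SE), Isg15 with -0.63 ± 0.38 (SE) and the transcription factor Irf7 with -0.59 ± 0.24 (SE). These SEs are of the fit without a block, where limma's adjusted p over the list was 0.185, 0.175, 0.213 and 0.154. With the block it was 0.0253, 0.0150, 0.0150 and 0.0194. Stat2, with 0.07 ± 0.13 (SE), was the 1 member with a higher mean. The list's median differences within replicate numbers 1, 2 and 3 were -0.13, -0.41 and -0.36. The size rested mainly on 2 control arrays. The list's level was 0.43 and 0.20 in control replicates 2 and 3. In control replicate 1 it was -0.055, close to silenced replicate 2 (-0.088). Without control replicate 2 alone the median was -0.21, still called at the preset correlation.

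**Figure D1:**
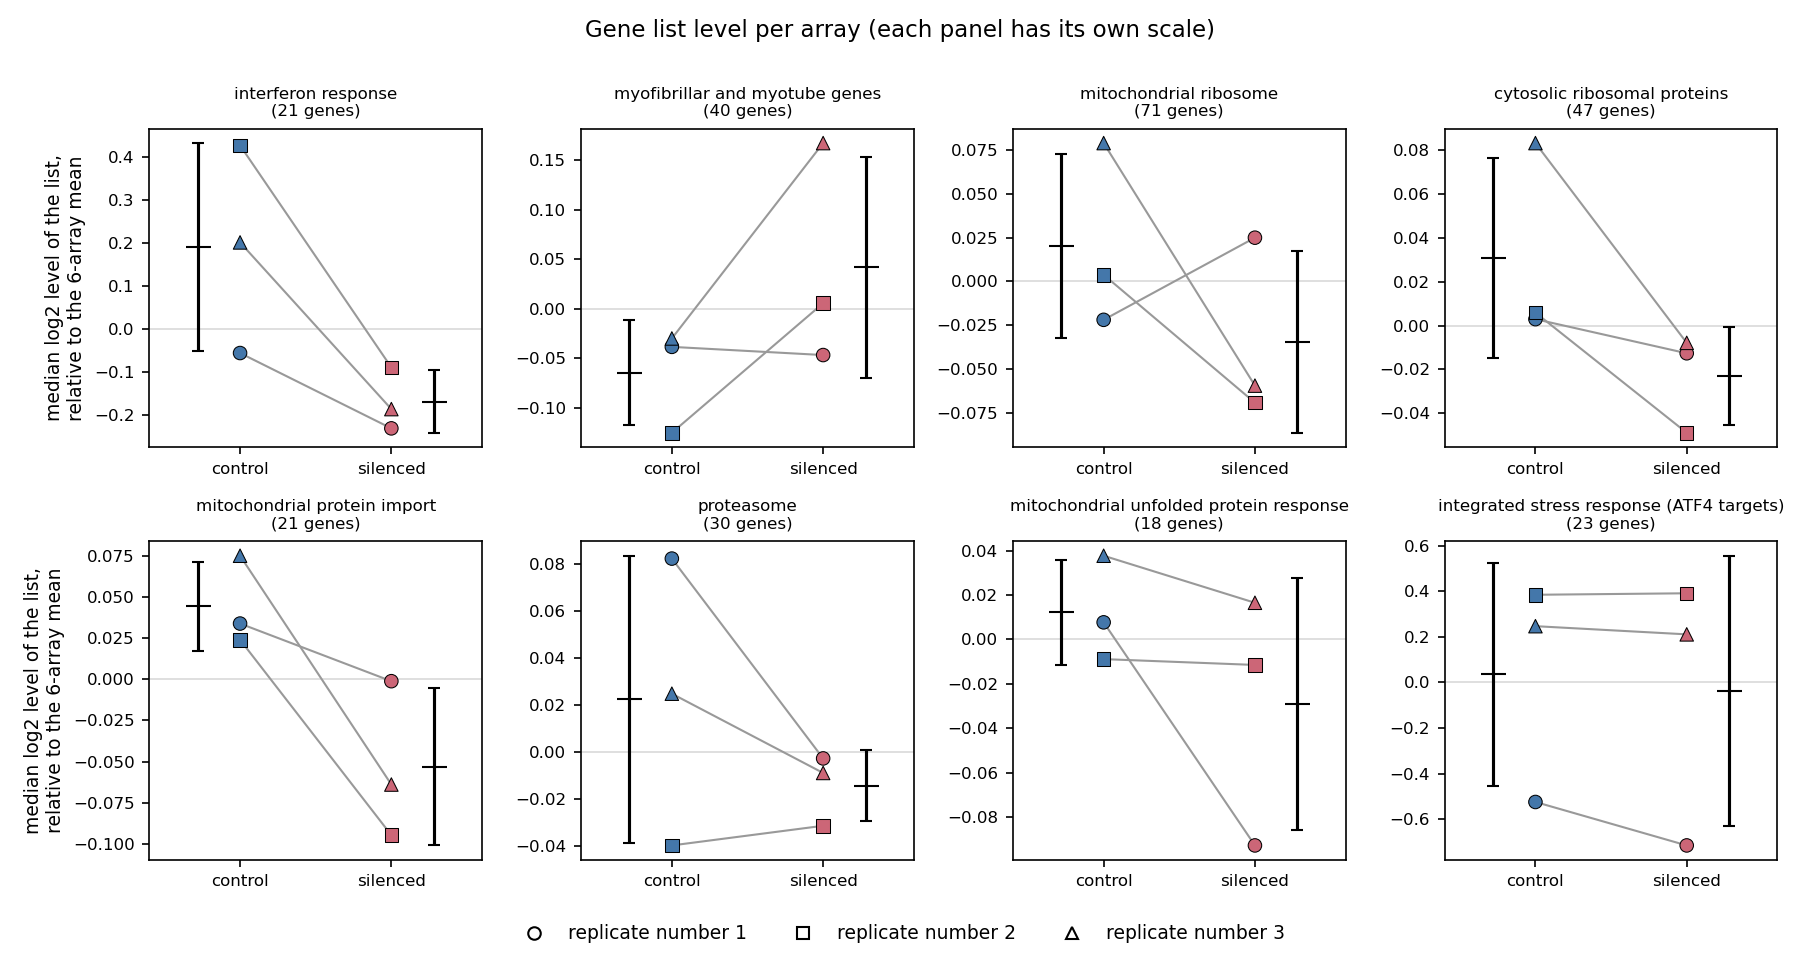
Level of 8 gene lists on each array, each panel on its own scale: the y axis is the median over the list's genes of the log2 level relative to the gene's mean over the 6 arrays, circles, squares and triangles are replicate numbers 1, 2 and 3, grey lines join same-numbered arrays, and black bars are the group mean ± SD (n = 3). All 3 silenced arrays lie below all 3 control arrays for the interferon list, while the ATF4-target list separates both arrays numbered 1 from the other 4 regardless of group.

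Genes of the contractile apparatus and the myotube rose as a list, with a median difference of 0.13 log2 over 40 tested members (camera, adjusted p = 0.00186; adjusted p = 0.892 with an estimated correlation). Of the 40, 29 had a higher and 11 a lower mean in silenced arrays, and 0 passed limma adjusted over the list alone. Myh1, an adult fast myosin heavy chain, read 10.88 ± 0.07 in control and 11.23 ± 0.11 in silenced arrays (limma, adjusted p = 0.149 over the list). Myh3, the embryonic myosin heavy chain, read 11.28 ± 0.08 and 11.53 ± 0.05 (limma, adjusted p = 0.149 over the list). Chosen after their values were seen, Neb, which encodes the thin filament ruler nebulin, differed by 0.33 ± 0.11 (SE), Cacna1s, the muscle calcium channel subunit, by 0.32 ± 0.11 (SE), and Mymk, the fusion protein myomaker, by 0.22 ± 0.08 (SE). Chosen in the same way, the light chain gene Myl1 differed by 0.01 ± 0.09 (SE), the troponin gene Tnnt3 by 0.02 ± 0.08 (SE) and the actin gene Acta1 by 0.05 ± 0.07 (SE). Lists of other states of these cells were not called: undifferentiated myoblast markers had a median of 0.023 (adjusted p = 0.761), myogenic regulators 0.10 (adjusted p = 0.627) and cell cycle genes -0.028 (adjusted p = 0.453). The contractile list's median differences within replicate numbers 1, 2 and 3 were 0.021, 0.12 and 0.20. The groups overlapped per array: silenced replicate 1 (-0.047) lay below control replicates 1 (-0.039) and 3 (-0.030). Silenced replicate 3 was highest (0.17). The call on contractile genes was lost without silenced replicate 3 (median 0.047, camera adjusted p = 0.268) and without control replicate 2 (adjusted p = 0.0619).

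Ribosomal protein genes of both compartments fell as lists. The mitochondrial ribosome list had a median difference of -0.078 over 71 tested members, 52 of them lower and 19 higher (camera, adjusted p = 0.00186; adjusted p = 0.892 with an estimated correlation). Its members with the smallest p were Mrps22, at 7.84 ± 0.04 in control and 7.58 ± 0.05 in silenced arrays, and Mrpl48, at 7.58 ± 0.14 and 7.34 ± 0.06 (limma, adjusted p = 0.607 over the list for both). Within replicate number 1 the list's median was 0.040, the opposite direction, against -0.10 and -0.13 within numbers 2 and 3. The cytosolic ribosome list had a median of -0.057 over 47 members, 37 of them lower (camera, adjusted p = 0.00186; adjusted p = 0.892 with an estimated correlation). Rpl26 read 5.62 ± 0.04 in control and 5.26 ± 0.16 in silenced arrays, and Rpl7 read 11.34 ± 0.05 and 11.19 ± 0.09. Ribosomal protein genes have many processed copies in the genome, so their probe sets can carry signal of more than 1 locus. Both calls were lost without control replicate 3, with adjusted p = 0.0896 and a median of -0.048 for the mitochondrial list and adjusted p = 0.228 and a median of -0.028 for the cytosolic list, whose median was -0.037 without silenced replicate 2.

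The mitochondrial protein import list fell with a median of -0.093 over 21 members, 16 of them lower (camera, adjusted p = 0.0228; adjusted p = 0.744 with an estimated correlation). Dnajc19, a cochaperone of the inner membrane import motor, read 7.82 ± 0.16 in control and 7.44 ± 0.16 in silenced arrays. Timm8a1, an intermembrane space chaperone, read 7.13 ± 0.18 and 6.83 ± 0.17. The proteasome list fell with a median of -0.041 over 30 members, 22 of them lower (camera, adjusted p = 0.0353; adjusted p = 0.892 with an estimated correlation), and Psmb3 read 9.78 ± 0.09 in control and 9.59 ± 0.06 in silenced arrays while Psmd13 read 8.87 ± 0.12 and 8.67 ± 0.10. With the replicate number as a block the proteasome list was no longer called (adjusted p = 0.0742). The import call was lost without silenced replicate 2 (median -0.073), control replicate 1 (-0.058) or control replicate 3 (-0.060), and its median was -0.048 without control replicate 2. The proteasome call was lost without silenced replicate 1 (-0.052) or 2 (-0.039) or control replicate 1 (-0.020) or 3 (-0.031), and its median was -0.078 without control replicate 2. Without both arrays numbered 1, neither list was called.

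Nuclear-encoded OXPHOS genes, the subunits of the respiratory chain and ATP synthase, were not called in any of the 5 complexes. The list medians were -0.051 for complex I (34 members, adjusted p = 0.112), -0.077 for complex II (4 members, adjusted p = 0.662), -0.060 for complex III (8 members, adjusted p = 0.430), -0.053 for complex IV (13 members, adjusted p = 0.254) and -0.0089 for complex V (15 members, adjusted p = 0.627), all by camera. Complex I was called as lower after repeated quantile normalization (adjusted p = 0.0499), without silenced replicate 3 (adjusted p = 0.0441) and without control replicate 2 (adjusted p = 0.00744). Over all 74 genes, a grouping chosen after the data were seen, 50 had a lower and 24 a higher mean in silenced arrays. The mean level per array was 9.36 ± 0.04 in control and 9.31 ± 0.03 in silenced arrays, a difference that an exact 2-sided permutation test did not separate from 0 (p = 0.3, where 3 against 3 allows no p under 0.1). Ndufb11 of complex I read 8.52 ± 0.0025 in control and 8.29 ± 0.13 in silenced arrays, and Ndufa9 read 8.67 ± 0.06 and 8.51 ± 0.03. Sdhb, the iron-sulfur subunit of complex II, differed by -0.15 ± 0.09 (SE) and Sdhc by 0.18 ± 0.14 (SE). Uqcr10 and Uqcrb of complex III differed by -0.18 ± 0.11 (SE) and -0.099 ± 0.083 (SE), Ndufa4 and Cox7a2 of complex IV by -0.18 ± 0.09 (SE) and -0.24 ± 0.12 (SE), and Atp5pb and Atp5l of complex V by -0.20 ± 0.09 (SE) and -0.17 ± 0.10 (SE). None of these passed limma over its list. The mtDNA-encoded subunits are not analysed here.

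Genes of the mitochondrial unfolded protein response were not called as a list, with a median of -0.023 over 18 members, 6 higher and 12 lower (camera, adjusted p = 0.662). The median was 0.027 without silenced replicate 1 and -0.047 without silenced replicate 2, and without control replicates 1 or 3 it was -0.0099 or -0.014. The matrix chaperonin genes Hspd1 and Hspe1 differed by -0.028 (95% confidence interval -0.28 to 0.22) and -0.018 (-0.31 to 0.27). The matrix chaperone Hspa9 differed by -0.0021 (-0.38 to 0.37), and the proteases Clpp and Lonp1 by 0.055 (-0.16 to 0.27) and -0.13 (-0.71 to 0.45). These intervals are of the fit without a block and include the spread between replicate numbers. Grpel1, the nucleotide exchange factor of Hspa9, differed by -0.19 ± 0.08 (SE) and the protease subunit Spg7 by 0.13 ± 0.09 (SE). The mtDNA maintenance list had a median of -0.0077 (18 members, adjusted p = 0.761), with Polrmt, the mitochondrial RNA polymerase, at 6.67 ± 0.09 in control and 6.90 ± 0.15 in silenced arrays, the helicase gene Twnk at 4.98 ± 0.16 and 5.21 ± 0.04, and Tfam differing by 0.046 (-0.15 to 0.24). Regulators of mitochondrial biogenesis were not called (median -0.0029, 12 members, adjusted p = 0.904), and Ppargc1a differed by -0.053 (-0.40 to 0.29). In that list, 2 genes passed limma adjusted over the list alone in opposite directions and are named after their values were seen. Prkaa2, a catalytic subunit of the kinase AMPK, read 6.14 ± 0.10 in control and 6.59 ± 0.18 in silenced arrays, and the deacetylase gene Sirt1 read 6.85 ± 0.09 and 6.41 ± 0.19 (adjusted p = 0.0365 over the list and 0.871 over all genes for both).

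**Figure D2:**
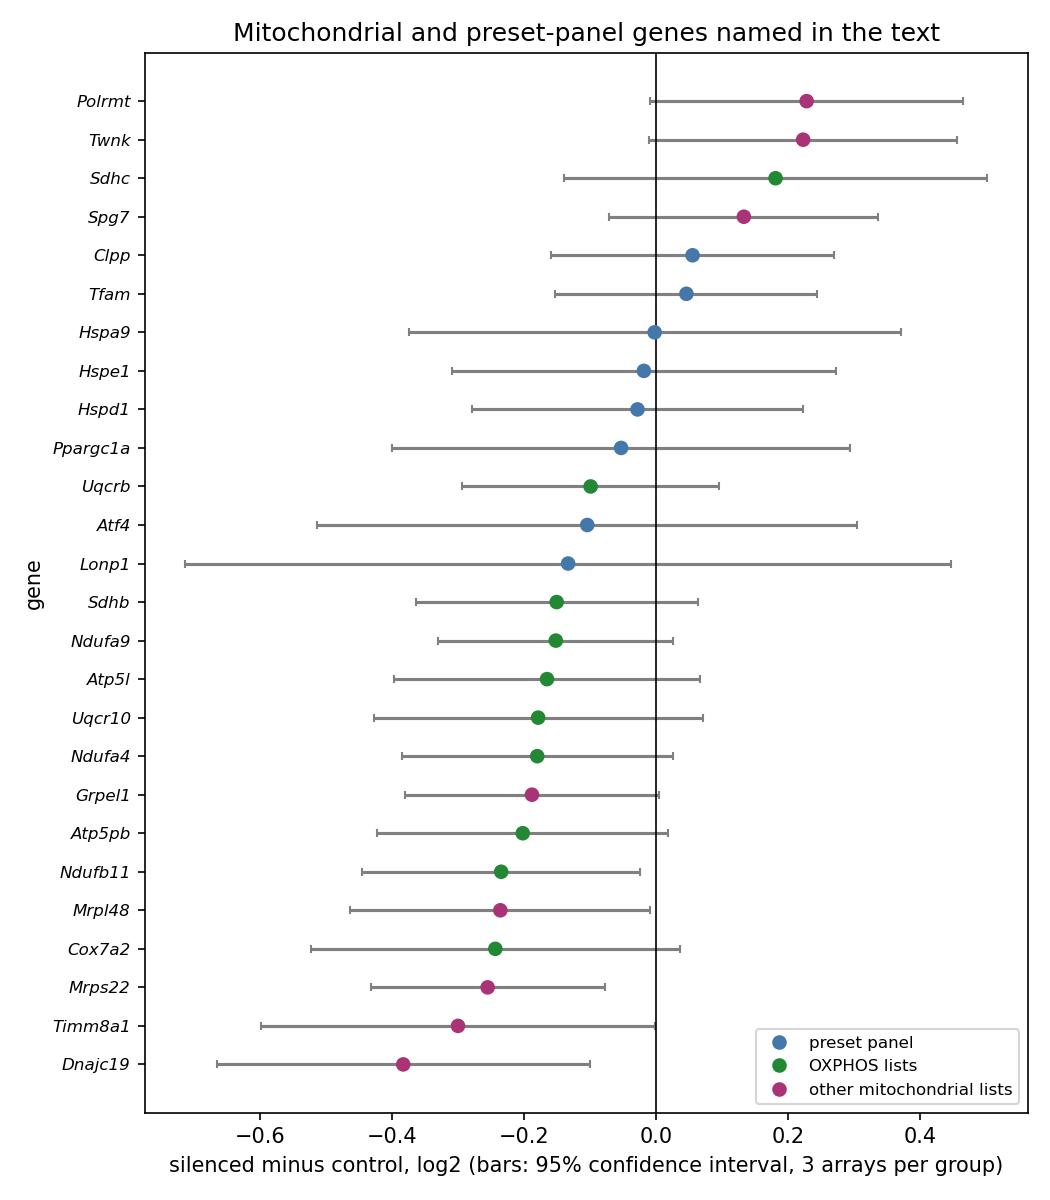
Differences of 26 mitochondrial and preset-panel genes: the x axis is silenced minus control in log2, points are limma estimates coloured by the list that named them, and bars are 95% confidence intervals (n = 3 per group). The interval includes 0 for 21 genes and lies below 0 for 5, Dnajc19, Timm8a1, Mrps22, Mrpl48 and Ndufb11, of which none passed the adjusted threshold.

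Targets of ATF4, the transcription factor of the integrated stress response, were not called without a block (median -0.089, 23 members, camera, adjusted p = 0.453) and fell in silenced arrays with the replicate number as a block (adjusted p = 0.00774, and 0.836 with an estimated correlation in the same fit). The difference within replicate number 1 was -0.17, against 0.00096 and -0.027 within numbers 2 and 3, and without both arrays numbered 1 the list was not called (adjusted p = 0.864). Leaving out silenced replicate 1 turned the direction, with a median of 0.31 (adjusted p = 0.00571), and the median was also above 0, with no call, without control replicate 2 (0.095) or 3 (0.021), while the list was called as lower without silenced replicate 2 (-0.28), control replicate 1 (-0.42) or silenced replicate 3 (-0.23). This list differed far more between replicate numbers than between groups, with per-array levels of -0.037 ± 0.594 in silenced and 0.036 ± 0.490 in control arrays. Ddit4 differed by -0.29 ± 0.19 (SE), Psph, an enzyme of serine synthesis, by -0.23 ± 0.36 (SE), and Atf4 itself by -0.10 (-0.51 to 0.31). These errors are of the fit without a block and include the spread between replicate numbers. With the block, limma's unadjusted p was 0.0123 for Ddit4, 0.177 for Psph and 0.236 for Atf4. The adjusted p over all genes was 0.464, 0.584 and 0.627. Over all tested genes the first principal component held 46.8% of the variance and placed both arrays numbered 1 (-19.3 silenced, -15.0 control) apart from the other 4 (7.29 to 9.96). The second held 17.9% and placed the 3 silenced arrays (-0.24, -12.7 and -4.96) below the 3 control arrays (1.72, 4.81 and 11.4).

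The remaining lists were not called by camera. Among metabolic lists the medians were -0.014 for the TCA cycle, -0.046 for fatty acid oxidation, 0.042 for glycolysis and 0.044 for cholesterol and lipid synthesis (adjusted p = 0.805, 0.581, 0.662 and 0.453). Among stress lists they were 0.032 for the ER unfolded protein response, 0.012 for the cytosolic heat shock response, -0.023 for antioxidant genes, -0.035 for the hypoxia response, 0.027 for p53 targets and -0.027 for NF-kB and cytokine genes (adjusted p = 0.731, 0.904, 0.430, 0.662, 0.761 and 0.731). Mitochondrial dynamics and mitophagy had a median of 0.0042 (adjusted p = 0.838), muscle atrophy genes 0.028 (adjusted p = 0.997) and circadian clock genes -0.027 (adjusted p = 0.761). Markers of other cell types had medians of 0.039 for fibroblasts and matrix, -0.033 for adipocytes (3 tested members) and 0.099 for osteoblasts and chondrocytes (5 tested members), each with adjusted p = 0.761. Single arrays decided some of these calls. Cell cycle genes were called as lower without silenced replicate 1 (adjusted p = 3.02e-05) or control replicate 3 (adjusted p = 0.00579), and cholesterol genes as higher without silenced replicate 2 (adjusted p = 0.00341) or control replicate 1 (adjusted p = 0.000895). Antioxidant genes were called as lower without control replicate 2 (adjusted p = 0.0387), and osteoblast and chondrocyte markers as higher without both arrays numbered 1 (adjusted p = 0.0386). For the p53, mitophagy and muscle atrophy lists camera's direction was down while the median was above 0, and for biogenesis regulators the mean was 0.010 while camera's direction was down.

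The single genes with the smallest p are given as values, since none passed limma's adjusted threshold (adjusted p = 0.487 for Zar1 and Zfp975, 0.871 for the others). On the higher side, Zar1, a gene known from oocytes, read 4.18 ± 0.035 in control and 4.92 ± 0.14 in silenced arrays, and Chrnb1, the beta subunit of the muscle acetylcholine receptor, read 9.09 ± 0.03 and 9.56 ± 0.11. Egr3, an immediate early transcription factor, read 5.93 ± 0.05 and 6.43 ± 0.14, and Acvr1b, a type I activin receptor, read 4.80 ± 0.09 and 5.32 ± 0.17. Lin37, B4galnt3, Zfp93, Stk36, Dusp22 and Lrrc56 differed by 0.46, 0.40, 0.48, 0.41, 0.36 and 0.55 log2, with SEs of 0.075, 0.073, 0.088, 0.084, 0.075 and 0.11. On the lower side, the zinc finger gene Zfp975 read 5.97 ± 0.02 in control and 5.29 ± 0.10 in silenced arrays. Ccl8, a chemokine gene, read 5.74 ± 0.14 and 5.09 ± 0.08, and Nmd3, an export adaptor of the large ribosomal subunit, read 8.62 ± 0.11 and 8.14 ± 0.16. Ifit1 belongs to this set as well. Snora34, Rad51b, H2bc9, Zfp758, Zbtb33 and Pcdhb15 differed by -0.47, -0.47, -0.36, -0.40, -0.38 and -0.38 log2, with SEs of 0.084, 0.092, 0.075, 0.087, 0.083 and 0.084. For all 20 the 3 silenced values lay apart from the 3 control values. Each was therefore on the same side in all 3 same-numbered pairs by construction, which adds no support. Histone, zinc finger and protocadherin genes have near-identical relatives that a probe set may not tell apart.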

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

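Chosen only after the data were seen were the fits without both arrays numbered 1, the replicate block with an estimated correlation, the unadjusted count with the block, and the test of all nuclear-encoded OXPHOS genes together. No gene passed limma's adjusted threshold under any of the alternatives run (0 genes with the replicate block, an intensity trend, array weights, repeated quantile normalization, centring, other filters, averaged probe sets, a minimum difference of 0.26 log2, without each array, and without both arrays numbered 1), and 542 passed without adjustment. The unadjusted count was 1168 with the replicate block, 1109 with array weights, 834 without a filter, 1160 without both arrays numbered 1, and between 272 (without control replicate 3) and 828 (without control replicate 1) without single arrays. Camera called 6 lists, and between 3 and 7 without single arrays. With an estimated correlation 0 were called: the adjusted p was 0.744 for the interferon and import lists and 0.892 for the myotube, both ribosome and proteasome lists. With fry 0 were called (0.901, and 0.941 for the proteasome), and with the replicate block and an estimated correlation 0 were called (0.836 for each). With the replicate block alone the proteasome was lost (0.0742) and the ATF4 targets were gained (0.00774), and the block changed no other call. Centring lost the proteasome (0.0568), and leaving out both arrays numbered 1 lost import (0.0534) and the proteasome (0.864). Leaving out single arrays gave adjusted p between 9.49e-14 and 1.35e-05 for interferon, 1.35e-05 and 0.268 for myotube genes, 0.000318 and 0.0896 for the mitochondrial ribosome, 0.000755 and 0.228 for the cytosolic ribosome, 0.00744 and 0.152 for import, 0.000719 and 0.581 for the proteasome, 0.409 and 0.957 for the mitochondrial unfolded protein response, and 0.000848 and 0.986 for ATF4 targets, which reversed to higher without silenced replicate 1 (0.00571). Leaving out an array leaves fewer samples, and otherwise the cause was not tested. Of 794 values of 54 named genes under alternatives, 0 changed a call at limma's adjusted threshold and 21 changed direction; of 364 values of the 26 other lists, 9 changed a call and 46 changed direction without one. Repeated quantile normalization moved the median of all genes from 0.0089 to 0.0097 and centring to 0.018. The 3' UTR seed match and mtDNA comparisons and their alternatives were not run. The number of arrays limits precision: simulated changes of 0.5 log2 were recovered for 17.9% of genes without a block and 31.3% with the replicate block.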

Other observations

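The comparison of arrays numbered 1 with the others, and every test below except the random lists for the silenced comparison and the splits counted by lists, was chosen after the values had been seen. The first principal component (46.8% of the variance) set arrays numbered 1 apart. The second (17.9%) parted the groups, which chance does for 10% of 3 against 3 comparisons. On it the arrays numbered 1 lay close together (-0.24 silenced, 1.72 control), on an axis from -12.7 to 11.4. In the blocked limma fit, 352 of 11292 genes differed between replicate numbers (F test, adjusted over all genes), and 2305 at an unadjusted p under 0.05. In the same fit 0 genes differed between groups after adjustment and 1168 at an unadjusted p under 0.05. ATF4 targets were lower in both arrays numbered 1: 17 of the 23 tested members passed the F test (Fisher's exact test, 1-sided, adjusted p = 4.9e-20 over 34 lists, with genes that are not independent), and 21 passed, all lower, for number 1 against the others. By camera the list was called for that contrast at the preset correlation, with adjusted p = 0.64 with an estimated correlation. Slc7a11, the cystine transporter, read 4.76 and 4.92 on the silenced and control arrays numbered 1 against 7.10 ± 0.15 (SD) on the other 4, 4.78-fold lower. Trib3, a pseudokinase induced by ATF4, read 6.38 and 7.21 against 8.83 ± 0.13, Cth, which makes cysteine, 6.54 and 6.88 against 8.70 ± 0.20, and Fgf21, a hormone that muscle releases under mitochondrial stress, 7.94 and 8.28 against 9.69 ± 0.10. Vldlr, Chac1 and Pck2 were 3.87-fold, 2.47-fold and 2.60-fold lower. Lonp1 was the 1 of 18 genes of the mitochondrial unfolded protein response to pass the F test, at 7.75 and 7.91 against 8.50 ± 0.10, and 3 passed as lower for number 1 against the others, Lonp1, Dnaja3 and Hspa9, named after their values were seen.

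Cell cycle and sterol genes differed in the opposite direction. In the cell cycle list 14 of 32 members passed the F test between numbers (Fisher's exact test, adjusted p = 3.05e-12) and 10 passed, all higher, for number 1 against the others (camera, adjusted p = 0.64 with an estimated correlation), among them Ccne1, the G1/S cyclin, at 7.68 and 7.49 against 6.83 ± 0.14, and the replication licensing gene Mcm3 at 8.30 and 8.25 against 7.57 ± 0.08. The F test covers any difference between numbers, and the genes that passed the 2 tests were not all the same. Top2a, named after its values were seen, passed only the F test, with number 3 lowest. It read 9.73, 9.58 and 8.96 on silenced arrays 1, 2 and 3 and 9.88, 9.61 and 9.30 on control arrays. In the cholesterol and lipid list 9 of 22 passed the F test (Fisher's exact test, adjusted p = 9.89e-08) and 9 passed, all higher, for number 1 against the others (camera, adjusted p = 0.64 with an estimated correlation), among them Stard4, 1.94-fold, Insig1, 1.81-fold, and Hmgcs1, which makes the sterol precursor HMG-CoA, 1.71-fold higher. Sqle, named in the same way, passed only the F test, with number 2 lowest. Its silenced arrays 1, 2 and 3 read 9.47, 8.78 and 9.20 and its control arrays 9.35, 8.78 and 9.09. No other list passed Fisher's exact test (the next was fibroblast and matrix markers, 4 of 25, adjusted p = 0.0576). Camera at the preset correlation also called 3 further lists for number 1 against the others, the interferon list (median -0.19, adjusted p = 0.0129) and fibroblast and matrix markers (-0.16, adjusted p = 0.0195) as lower and cytosolic heat shock genes as higher (0.17, adjusted p = 0.00761). With an estimated correlation their adjusted p = 0.723, 0.64 and 0.64; the interferon list was thus called between numbers as well as between groups, in both cases only at the preset correlation.

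The lower ATF4-target list in arrays numbered 1 was weighed against 3 explanations. A drift of genes at the same signal level is argued against, since the ATF4-target median lay at percentile 0 of 10000 random lists matched on mean expression. Random lists hold unrelated genes, so percentiles here and below speak only to drift and not to genes of a list varying together. A lower share of myotubes that lowers both lists alike is argued against as well for this list. The ATF4-target median (-0.96) lay 0.92 log2 below the myotube median (a difference of -0.92, 95% bootstrap interval over genes -1.24 to -0.61). That interval resamples genes and does not measure the spread between cultures. A share that moves the lists unequally was not tested. Whether such a share adds to the higher cell cycle list (median 0.45) was not tested. For number 1 against the others, myoblast markers had a median of 0.086, myogenic regulators -0.093 and myotube genes -0.037. Camera at the preset correlation called none of these last lists. A culture or handling step shared by same-numbered arrays stays open, since the lowest same-number correlation (0.35) cannot decide it: number 1 standing apart in both groups itself raises these correlations. The design names no biological difference between the numbers, and apart from the share of myotubes none was tested.

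The lower interferon list in silenced arrays was set against drift and against a single array. Its median lay at percentile 0 of the matched random lists, which argues against drift, and without control replicate 2, the highest array, the median was -0.21 with a camera adjusted p of 2.32e-06 at the preset correlation, which argues against that array as the whole cause. Camera at the preset correlation also called the list in 3 of the other 9 splits (adjusted p = 0.000304, 2.92e-07 and 0.000164), with absolute medians of 0.22, 0.39 and 0.22 against 0.32 in the real one, and the last of these parts all 3 pairs as the real one does, so the list also varies outside the groups. An effect of the inhibitor stays open as a hypothesis, as does one of the control oligonucleotide itself, since untransfected cells were not analysed here.

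The higher myotube list and lower mitochondrial ribosome list lay at percentiles 100 and 0 of matched random lists. The random lists had medians of 0.0054 and 0.013, which argues against drift at these signal levels. The percentiles do not test whether the genes of a list vary together for another reason. Of the 10 splits of the arrays into 3 and 3, 5 called at least as many lists as the real one, which called 6, and the highest other called 8. The splits are too few for a share under 0.05. For single genes at limma's adjusted threshold the real count was 0 and the highest other 0, so all 10 splits reach it by construction and the comparison decides nothing. The 4 splits with both arrays numbered 1 on one side called 5 to 8 lists and up to 1250 genes at an unadjusted p under 0.05 against 542 in the real one, which points to the structure by number. The 2 splits that part the arrays numbered 1 and set numbers 2 and 3 on opposite sides called 7 and 4 lists, with 260 and 302 such genes, so list calls do not follow number 1 alone. All counts of splits are from fits without a block. The 3 other splits that part all 3 pairs, as the real one does, called 0 to 4 lists, with 103, 422 and 227 such genes. With the replicate number as a block the real comparison also called 6 lists, a count with no blocked count of another split to set it against.

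Probe sets that name no gene or several genes, 6345 above the same level, gave 0 past limma's adjusted threshold and 274 at an unadjusted p under 0.05.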
